A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

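RNA from 3 wild-type and 3 PHO80-deletion samples of BY4741 was labelled with Cy3 and hybridised to 1-colour Agilent yeast arrays, per the labels' protocols. Per the file headers, the scanner output was made with Agilent Feature Extraction, for which the submitters' processing notes give version 10.1.1.1. The deposited values are spot intensity on a linear scale. The processed signal had its background subtracted within the array, per the file headers, and was not scaled between arrays. The series' value table holds 1 intensity per probe from the authors, with scale, centring and direction unstated. Set against the scanner files it was linear, uncentred and in the same direction (Pearson r of log2 values 0.997 to 0.999 across probes, median ratio 0.996 to 1.00). Its columns had medians of 1120, 1140 and 950.5 in wild type and 1120, 746.5 and 1670 in the deletion strain. How the spots of a probe were combined in it is not given in the sources used here.

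From each array, control spots and spots flagged as non-uniform or population outliers were left out (1.12% to 1.88% of probe spots). The log2 processed signal minus the array's 75th percentile was averaged over the spots of a probe. A probe was well above background on an array where the flag held for over 0.5 of its spots. Each gene had 1 probe. Systematic names were matched to RefSeq symbols of assembly R64, where 5756 of 6256 matched and 500 kept their systematic name. No genome build is named for the array, so no coordinates are given. Genes well above background on at least 3 of the 6 arrays, in either strain, were tested (5863 tested, 393 not).

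Groups and replicate numbers came from the labels. The design fixed before the data were examined counted 6 separate arrays. It was changed afterwards. Over 5664 probes above background on all arrays, the squared difference between 2 arrays of a strain was set against the variance among their spots, and 2 arrays were averaged as 1 sample where its median did not exceed the value that spot noise gives. This rule was chosen after the counts of the 6-array fit and the pairwise values had been seen. It merged arrays 1 and 3 of each strain. For the wild-type arrays the 3 pairs differ little (0.634, 0.435 and 0.669), so all 3 may be technical repeats. The fits with 6 arrays and with the wild type as 1 sample are therefore given as alternatives.

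The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on 2 samples per strain, with 2 residual and 1.93 prior degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05. Mean ± SE are from this fit. Gene lists with at least 3 tested members, 28 in all, were written before the data were examined and tested with camera (preset correlation 0.01, adjusted over the lists), and again with an estimated correlation and with fry. Of their members 4 were not on the array. With an estimated correlation camera takes its p from the 2 residual degrees of freedom. A call lost there therefore does not show that a list was unchanged. Named genes followed a rule set before the data were examined. It took PHO80, the 10 largest rises and 10 largest falls among called genes that were above background on all arrays of the brighter strain and whose strains did not overlap, up to 3 called members per called list by p (4 for the PHO regulon), and 13 genes always reported (PHO5, PHO84, PHO4, PHO81, GRE3, XYL2, XKS1, PHO13, ACT1, HIS3, LEU2, MET17 and URA3). A further 7 lists were added after the data were seen and were adjusted over these 7.

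The fit was tested on simulated data for this comparison, with 2 samples per strain, 5863 genes, 200 of them changed, and 20 runs. With equal spread in both strains it called 42.9% of genes changed by 2 on the log2 scale, 0.377% of those changed by 1 and 0% of those changed by 0.5, and 4.71% of the calls were unchanged genes. With each strain's own measured spread, which was larger in the deletion strain, it called 62.6%, 41.0% and 3.71%, and 26.9% of the calls were unchanged genes, above the nominal 5%. Of unchanged genes it called 0.458%, against 0.0247% with equal spread. In these runs the measured spreads were shuffled among genes. The 26.9% also depends on how few genes were changed, and cannot be carried over to the 3152 calls in the data. A list shifted by 1 was called in 20 of 20 runs under either spread, and other lists in 0 of 540 tests. The simulated genes were drawn independently of each other. The 0 of 540 therefore cannot show how often lists of correlated genes are called falsely. In the data, the estimated correlation of the called lists ran from -0.063 (mating type a) to 0.599 (glycolysis). Alternatives covered scaling, background correction, the filter on dim probes, the variance model, the test, the replicate block, each left-out array, the value table, the set test and the size threshold. Figures were drawn with matplotlib 3.10.9.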

Results

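Messenger RNA levels were measured in the yeast Saccharomyces cerevisiae, in the haploid laboratory strain BY4741 and in the same background lacking PHO80, after 6 h of fermentation of 80 g/l xylose. PHO80 encodes the cyclin of the Pho85 kinase, which keeps the transcription factor Pho4 out of the nucleus when phosphate is plentiful. The labels list 3 wild-type and 3 deletion samples, each hybridised in 1 colour (Cy3) to an Agilent array that carried 6256 gene probes in 7 spots each. The 75th percentile of the processed signal ranged from 2404 to 5011 across the 6 arrays, and 92.0% to 94.6% of probes were well above background. No spot was saturated. Arrays 1 and 3 of each strain differed by less than the noise between repeated spots, with a median squared difference over the spot variance of 0.435 in wild type and 0.412 in the deletion strain, where spot noise alone gives 0.484. They were therefore counted as 1 sample, which left 2 samples per strain. Wild-type array 2 lay just above spot noise from arrays 1 and 3 (0.634 and 0.669), whereas deletion array 2 lay far from its companions (88.6 and 94.8). The labels do not say that the replicates came from separate cultures, so the p-values and SE measure only the spread between these samples. That spread was pooled over both strains. In wild type it was near spot noise and may not stand for the spread between cultures. The small number of samples limits the precision.

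The comparison asked how gene expression in the PHO80-deleted strain differed from wild type during xylose fermentation. PHO80 itself was measured at -2.93, -2.83 and -2.86 on the wild-type arrays (log2 signal relative to the array's 75th percentile). On the 3 deletion arrays it read -9.41, -9.85 and -9.96 and was not well above background on any of them. PHO80 was thus at least 27.4-fold lower in the deletion strain (adjusted p = 0.00153, limma). This and every other "at least" fold sets the bright strain's mean against the dim strain's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

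The difference between the strains was broad. Of 5863 genes tested, 1123 were higher and 2029 lower in the deletion strain by limma at the adjusted p threshold of 0.05, and 654 of the higher and 1411 of the lower genes changed at least 2-fold. The 10 genes with the largest fitted rise included SPL2 and PHM6 of the phosphate regulon, with log2 fold changes of 6.60 ± 0.21 and 5.65 ± 0.32 (SE), and the secreted acid phosphatase gene PHO5 (4.48 ± 0.21). NRS1 rose by 4.62, GPX2 (a glutathione peroxidase) by 4.58, FLO5 (a flocculation lectin) by 4.41, HXT3 (a low-affinity glucose transporter) by 4.30 and FIT2 (a cell wall mannoprotein that aids siderophore iron uptake) by 4.17. FRM2 was at least 15.7-fold higher and was above background on only 1 of the 3 wild-type arrays. AHT1 was not well above background on any wild-type array and was at least 6.06-fold higher. Its place among the 10 rests on a background reading, and its value is uncertain because it lies between the hexose transporter genes HXT4 and HXT1, which rose too. The 10 largest falls were all of mitochondrially encoded genes, described further on.

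The balance between rises and falls depended on the scaling. The median log2 fold change of all tested genes was -0.28 under the 75th percentile scaling, 0.01 when each array was centred on its median and 0.03 after quantile normalization. The higher genes made up 35.6%, 50.4% and 52.8% of the calls under these scalings. Gene lists are therefore given relative to the median of all tested genes. On 4806 genes (82.0%) the 3 arrays of one strain all lay outside the range of the other, where chance gives 10% for 3 against 3, although arrays 1 and 3 of a strain are not independent. The counts depended on array 2 of each strain: they were 523 higher and 1122 lower without wild-type array 2, 2200 higher and 3289 lower without deletion array 2, and 519 and 1130 when all wild-type arrays were counted as 1 sample. In that last fit the counts of the gene lists below were within 1 gene of those without wild-type array 2. The p-values of these fits with 1 sample in a strain take their spread from the other strain alone. Without deletion array 2 that is the spread of the wild-type arrays, near spot noise. Calls and adjusted p without that array, here and below, are therefore no evidence of change between cultures. Each strain was on its own slide, scanned on its own, so slide and strain cannot be told apart.

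The phosphate (PHO) regulon, the genes that Pho4 activates in low phosphate, rose together. Of its 22 tested members 20 were higher and none lower, and adjusted over the list alone 20 were higher and 2 lower. The median log2 fold change was 2.53, which is 2.82 above the median of all genes. The high-affinity phosphate transporter gene PHO84 rose by 3.80 ± 0.20, PHO81 (the inhibitor of the Pho80 and Pho85 kinase) by 2.99 ± 0.10, and VTC4 and VTC1 of the vacuolar polyphosphate polymerase complex by 2.76 ± 0.12 and 2.73 ± 0.12. PHM7 and PPN1 had log2 fold changes of -1.02 and -0.51 and did not pass over all genes (adjusted p = 0.0623 and 0.0685 by limma). Without deletion array 2, which leaves 1 deletion sample, they were -0.59 and -0.32. PHM7 was called lower with normexp background correction (adjusted p = 0.0495). The list also had 2 lower genes beside 20 higher with 6 separate arrays, the design fixed in advance. PHO4, which encodes the activator, had a log2 fold change of 0.23 ± 0.13 (adjusted p = 0.201), against 0.52 (adjusted p = 0.0468) with median centring and 0.96 (adjusted p = 0.0114) with quantile normalization. With 6 separate arrays it was also called (0.20, adjusted p = 0.0314), and without deletion array 2 it was 0.17. The list was called by camera with a preset correlation (adjusted p = 3.07e-10) but not with a correlation estimated from the data (adjusted p = 0.31 with an estimated correlation). The estimate, -0.037, lay below the preset 0.01, so correlation among the list's genes does not account for the lost call.

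**Figure D1:**
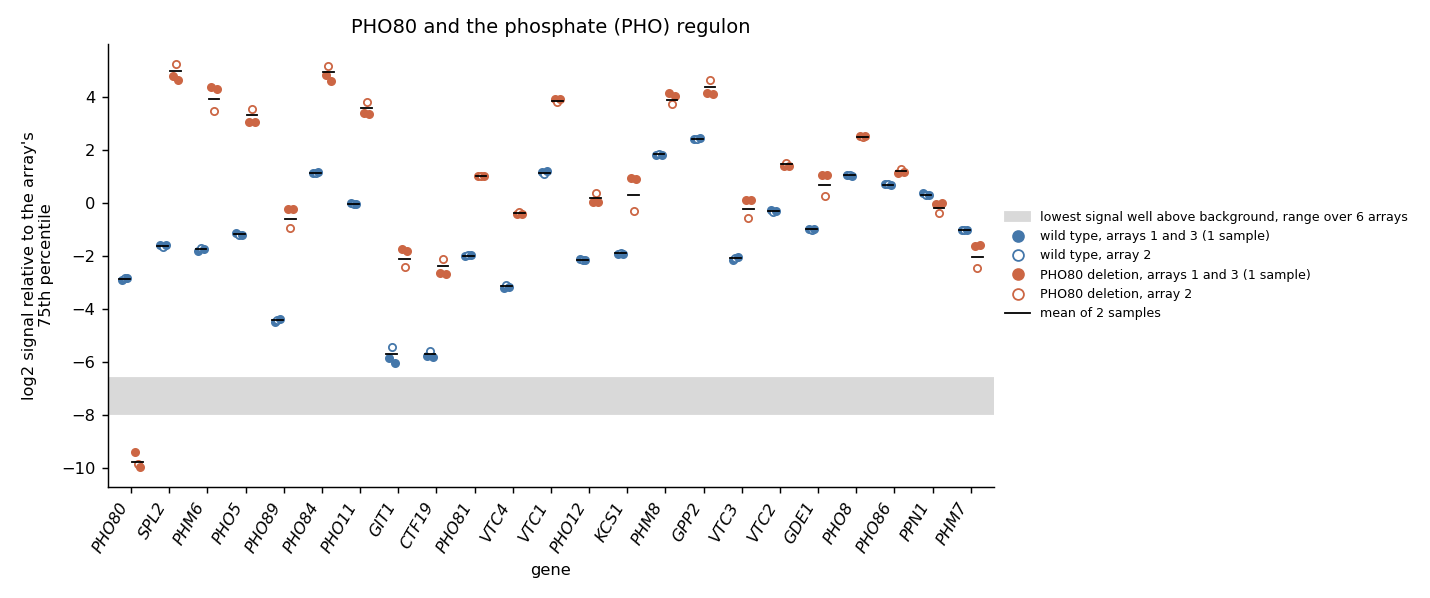
Log2 signal relative to each array's 75th percentile (y axis) for PHO80 and the 22 tested genes of the PHO regulon (x axis, ordered by fold change), in wild type (blue) and the PHO80 deletion (orange). Filled points are arrays 1 and 3, counted as 1 sample, open points array 2, bars the mean of 2 samples, and the grey band the lowest signals well above background; PHO80 lies below the band on the deletion arrays, and SPL2 has the largest rise (6.60).

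Genes of xylose and aldose use were mostly higher in the deletion strain, 8 of 10 tested, and 2 were lower, with the same counts adjusted over the list alone. XKS1, the xylulose kinase gene, rose by 2.70 ± 0.19 from an already bright wild-type signal of 3.12. On the deletion arrays XKS1 read 6.16, 5.62 and 5.87, close to URA3, a marker that BY4741 lacks (6.11, 5.55 and 5.90). URA3 was bright in wild type too (3.75). Whether the XKS1 signal came from the chromosomal gene alone was not tested. PHO13, a phosphatase gene, rose by 2.59 ± 0.13, the aldose reductase gene GRE3 by 1.95 ± 0.26, the xylitol dehydrogenase gene XYL2 by 1.65 ± 0.26 and the reductase gene YJR096W by 1.97 ± 0.12. The sorbitol dehydrogenase genes SOR1 and SOR2, named after their values were seen because they were the 2 that fell, were not well above background on any deletion array and were at least 4.73-fold and 3.91-fold lower. They are near-identical copies, so their separate values are uncertain. With normexp background correction 8 genes were higher and none lower, as SOR1 and SOR2 lost their calls (adjusted p = 0.0971 and 0.124). The list's genes stood a median of 0.20 higher on deletion array 2 than on arrays 1 and 3. The list median lay 1.97 above that of all genes (camera adjusted p = 0.00162, and adjusted p = 0.31 with an estimated correlation).

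Of 20 tested genes of hexose transport and its control, 11 were higher and 4 lower, also adjusted over the list alone. Beside HXT3, the glucose transporter genes HXT4 and HXT1 rose by 3.54 ± 0.23 and 3.32 ± 0.11. HXT14, named after its value was seen, fell below background in the deletion strain (at least 4.85-fold lower). The list had, without wild-type array 2, 8 higher and 2 lower, and without deletion array 2 13 and 7. With quantile normalization 13 were higher and 2 lower, and with normexp background correction 11 and 1, HXT14 losing its call (adjusted p = 0.0603). HXT genes share long stretches of sequence, so a probe may bind several transcripts. In glycolysis 9 of 19 genes were higher and none lower, and 7 were higher adjusted over the list alone. The glycolysis counts were 5 higher and 0 lower without wild-type array 2 and 16 and 2 without deletion array 2. On that array the glycolysis genes stood a median of 0.55 above arrays 1 and 3, the largest such shift of the 28 lists. PYK2 (a second pyruvate kinase) rose by 2.02 ± 0.17, PFK2 (a phosphofructokinase subunit) by 1.88 ± 0.12 and PFK27 (which makes the activator fructose 2,6-bisphosphate) by 1.88 ± 0.18. The medians of both lists lay above that of all genes, by 1.40 and 1.19 (camera adjusted p = 0.00676 and 2.11e-05). With an estimated correlation neither was called (adjusted p = 0.373 and 0.386 with an estimated correlation). The glycolysis median lay 0.84 above without deletion array 2 and 0.49 with quantile normalization, and that of hexose transport 0.86 without a filter on dim probes.

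**Figure D2:**
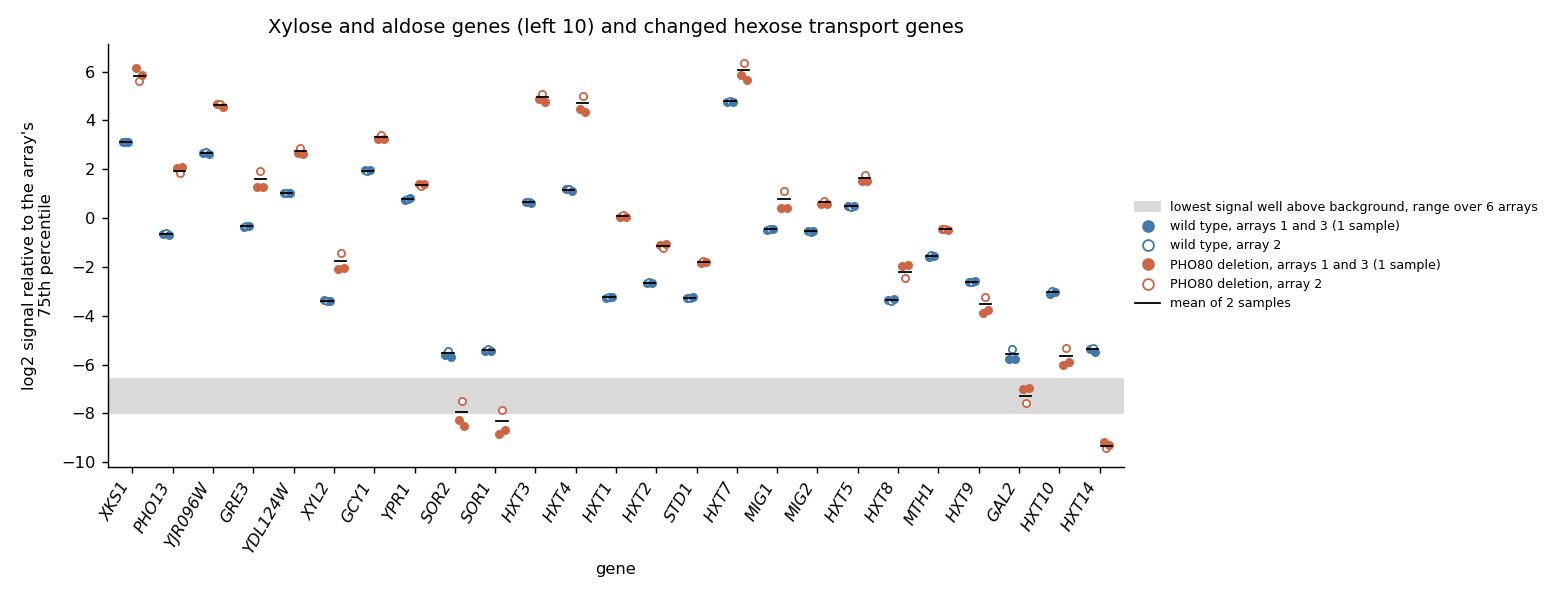
Log2 signal relative to each array's 75th percentile (y axis) for the 10 tested xylose and aldose genes and, to their right, the 15 hexose transport genes past the threshold (x axis), with colours, points, bars and band as for the PHO regulon. XKS1 rose by 2.70 and HXT3 by 4.30, whereas SOR1, SOR2 and HXT14 lay in or below the background band on the deletion arrays.

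Reserve carbohydrate and stress genes were higher as groups. For trehalose and glycogen 12 of 20 genes rose and 2 fell, with TPS3 of the trehalose synthase complex up by 0.97 ± 0.10, UGP1 (UDP-glucose synthesis) by 1.99 ± 0.23 and the glycogen synthase gene GSY2 by 1.35 ± 0.19. In the general stress response 18 of 30 rose and 3 fell, among the former SPS100 (3.02 ± 0.12), the heat shock gene SSA4 (2.53 ± 0.15) and DDR48 (2.26 ± 0.16). The 3 that fell were SSA3, HSP12 and SIP18 (-1.66, -1.35 and -1.64), named after their values were seen. Adjusted over the list alone the counts of both lists were the same. The medians lay 0.95 and 1.29 above that of all genes (camera adjusted p = 0.0014 and 1.65e-06), and each had an adjusted p = 0.31 with an estimated correlation. Only 4 trehalose and glycogen genes rose and 1 fell without wild-type array 2, where TPS3 lost its call (adjusted p = 0.101); without deletion array 2, 17 rose and 3 fell. With quantile normalization the medians lay 0.49 and 0.70 above that of all genes, with 11 higher and 1 lower trehalose and glycogen genes (15 and 1 with median centring). Stress genes stood a median of 0.31 higher on deletion array 2 than on arrays 1 and 3.

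Genes of iron uptake, sulfur metabolism, purine synthesis and autophagy also shifted upward. In the iron regulon 17 of 28 rose and 5 fell (18 and 6 adjusted over the list alone), including FIT2, the heme oxygenase gene HMX1 (2.49 ± 0.14) and the copper transporter gene CCC2 (1.85 ± 0.10). Of 27 sulfur and methionine genes 18 rose and 4 fell, including SAM2 (S-adenosylmethionine synthetase, 3.06 ± 0.14), MET22 (1.30 ± 0.12) and MET16 (1.15 ± 0.11). Of 21 purine and folate-linked genes 9 rose and 1 fell, including GCV1 of the glycine cleavage system (2.09 ± 0.11), ADE17 (1.91 ± 0.18) and ADE12 (0.94 ± 0.11). Of 21 autophagy genes 7 rose and 3 fell, including ATG19 (2.51 ± 0.19), ATG18 (1.83 ± 0.26) and ATG8 (1.35 ± 0.11). Adjusted over the list alone the sulfur, purine and autophagy counts were the same. The medians lay 0.95, 1.20, 0.82 and 0.48 above that of all genes, with camera adjusted p = 0.000232, 6.16e-05, 0.00791 and 0.0315, and each had an adjusted p = 0.31 with an estimated correlation. Without wild-type array 2 the counts higher and lower were 11 and 2 for iron, 11 and 0 for sulfur, 4 and 1 for purine and 4 and 2 for autophagy genes. Without deletion array 2 they were 19 and 8 for iron, 22 and 5 for sulfur, 13 and 3 for purine and 14 and 4 for autophagy genes. Quantile normalization gave 12 higher and 3 lower autophagy genes (median 0.85 above that of all genes), 17 and 1 sulfur genes (median 0.66 above) and 19 and 3 iron genes. Sulfur counts were 18 and 2 with median centring, and the purine median lay 0.48 above with normexp background correction. Autophagy genes stood a median of 0.345 lower on deletion array 2 than on arrays 1 and 3. With wild-type array 2 left out the autophagy list (adjusted p = 0.0644) and ADE12 (adjusted p = 0.0931) were not called.

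The largest group to fall was that of cytosolic ribosomal proteins. Of 137 tested, 125 were lower and 1 higher (131 and 1 adjusted over the list alone), with a median log2 fold change of -2.03, which is -1.75 relative to all genes. RPL43B fell (-3.64 ± 0.10), as did RPS22A (-3.53 ± 0.11) and RPS10A (-3.40 ± 0.11). The exception, RPL15B, rose by 0.54 (0.84 with median centring; named after its value was seen) and lost its call without wild-type array 2 (adjusted p = 0.37). Ribosomal protein genes stood a median of 0.33 higher on deletion array 2 than on arrays 1 and 3. Many of these genes have near-identical copies that a probe may not separate. Of 50 ribosome biogenesis genes 35 were lower and 1 was higher (36 and 1 adjusted over the list alone), with a median of -1.10 relative to all genes. Without deletion array 2, 2 ribosomal protein genes and 4 ribosome biogenesis genes were higher and 132 and 44 lower; without wild-type array 2 none of either were higher and 121 and 28 were lower. The box C/D nucleolar protein genes NOP58 (-2.03 ± 0.11) and NOP56 (-2.04 ± 0.13) fell, and so did IMP3 (-2.08 ± 0.13, but -1.17 with quantile normalization, where 2 genes of the list were higher and 29 lower). Camera gave adjusted p = 7.41e-18 and 2.27e-05 for these lists. Their estimated correlations were 0.244 and 0.0362, and neither was called with these (adjusted p = 0.314 and 0.31 with an estimated correlation).

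Ergosterol synthesis and the genes specific to mating type a were lower too. Of 25 ergosterol genes 16 fell and 1 rose (17 and 1 adjusted over the list alone). ERG11, the lanosterol demethylase gene, fell (-2.94 ± 0.11), as did ERG5 (-2.40 ± 0.11) and ERG10 (-1.64 ± 0.11). Of the 7 genes specific to mating type a, 6 fell and none rose (7 fell adjusted over the list alone), including STE6 (-1.91 ± 0.14), AGA2 (-1.97 ± 0.15, but -1.02 with quantile normalization and -1.06 with normexp background correction) and the pheromone gene MFA2 (-0.94 ± 0.12). The medians lay -0.48 and -0.66 relative to all genes (camera adjusted p = 0.00676 and 0.0252), and each had an adjusted p = 0.31 with an estimated correlation. The counts were 9 lower and 0 higher ergosterol genes and 3 lower mating genes without wild-type array 2. Without deletion array 2, 21 ergosterol genes fell and 3 rose and 7 mating genes fell. Ergosterol counts were 15 lower and 2 higher with quantile normalization (median -0.73 relative to all genes) and 11 and 2 with median centring. The mating list was not called with quantile normalization (adjusted p = 0.112) or without wild-type array 2 (adjusted p = 0.108), and MFA2 was not called without that array (adjusted p = 0.16).

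**Figure D3:**
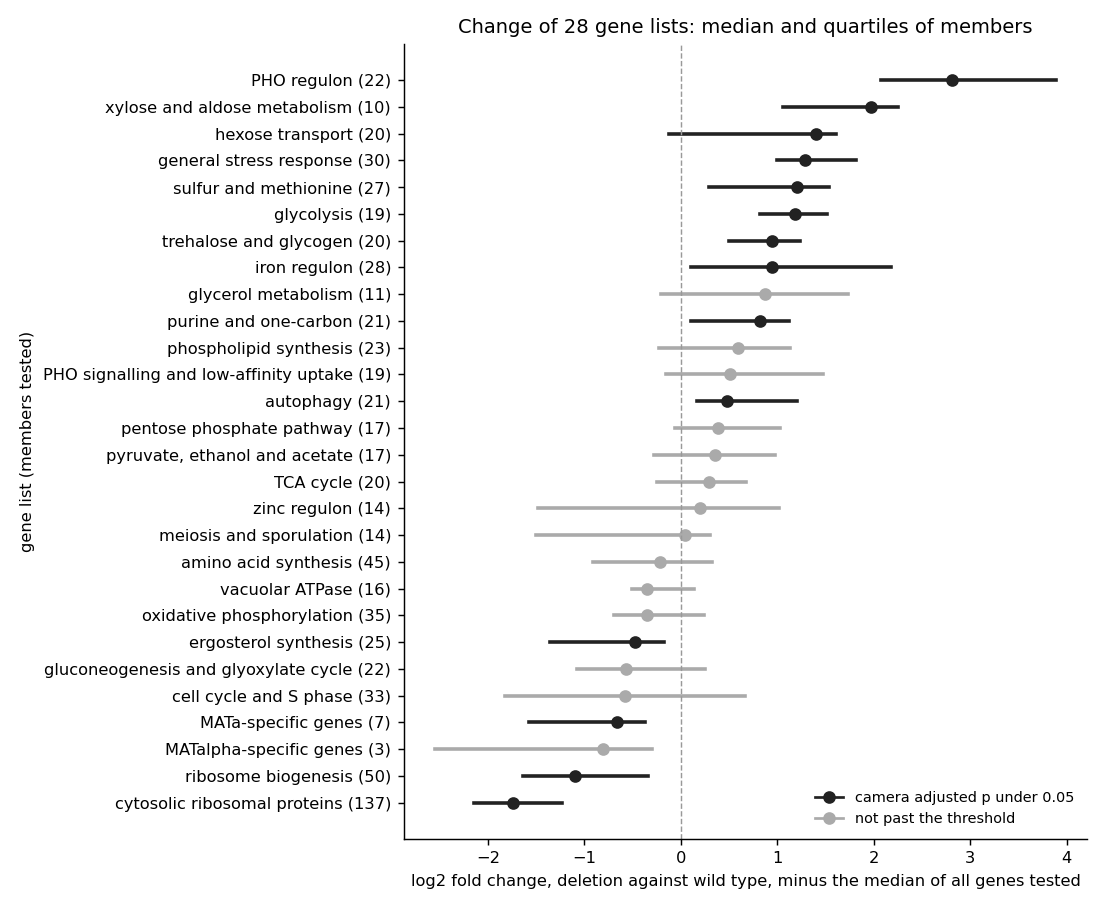
Median (point) and quartiles (line) of the log2 fold change, deletion against wild type, minus the median of all tested genes (x axis), for the 28 gene lists (y axis, members tested in parentheses). Black marks the 14 lists past a camera adjusted p of 0.05 with a preset correlation, from the PHO regulon at 2.82 to cytosolic ribosomal proteins at -1.75; with an estimated correlation none passed.

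The other 14 lists were not called by camera. Phosphate signalling and low-affinity uptake had 8 genes higher and 4 lower of 19 (adjusted p = 0.136), the pentose phosphate pathway 6 and 4 of 17 (0.113), pyruvate, ethanol and acetate metabolism 6 and 4 of 17 (0.237), and glycerol metabolism 5 and 3 of 11 (0.0774). The TCA cycle had 3 higher and 5 lower of 20 (0.547), oxidative phosphorylation encoded in the nucleus 5 and 16 of 35 (0.204), gluconeogenesis and the glyoxylate cycle 2 and 11 of 22 (0.175), and the vacuolar ATPase 1 and 8 of 16 (0.175). Amino acid synthesis had 7 and 21 of 45 (0.112), phospholipid synthesis 8 and 6 of 23 (0.0657), the zinc regulon 4 and 5 of 14 (0.68), and the cell cycle 8 and 19 of 33 (0.166). Genes specific to mating type alpha had 0 and 2 of 3 (0.204) and meiosis and sporulation 1 and 5 of 14 (0.585). Adjusted over the list alone these counts changed by at most 2 genes in a list, the largest change being 10 higher phospholipid genes. Without wild-type array 2 the counts higher and lower were 4 and 1 for the pentose phosphate pathway, 3 and 1 for pyruvate, ethanol and acetate, 2 and 3 for the TCA cycle, 1 and 8 for oxidative phosphorylation and 0 and 8 for gluconeogenesis. They were also 0 and 2 for the vacuolar ATPase, 3 and 12 for amino acids, 4 and 3 for phospholipids, 5 and 13 for the cell cycle and 0 and 1 for mating type alpha. Without deletion array 2 the counts higher and lower were 10 and 7 for phosphate signalling, 8 and 7 for the pentose phosphate pathway, 7 and 9 for pyruvate, ethanol and acetate, 8 and 8 for the TCA cycle, 9 and 26 for oxidative phosphorylation and 5 and 16 for gluconeogenesis. They were also 5 and 11 for the vacuolar ATPase, 11 and 32 for amino acids, 15 and 7 for phospholipids, 7 and 7 for zinc and 4 and 9 for meiosis. Quantile normalization turned the balance of meiosis and sporulation, to 4 higher and 2 lower. It also gave 8 and 12 for the cell cycle, 7 and 2 for pyruvate, ethanol and acetate, 3 and 20 for oxidative phosphorylation, 10 and 3 for phospholipids and 0 and 1 for mating type alpha. Median centring turned the TCA cycle, to 5 and 3, and gave 7 and 2 for pyruvate, ethanol and acetate, 5 and 11 for gluconeogenesis, 7 and 5 for zinc and 0 and 1 for mating type alpha. On deletion array 2 the median gene of phosphate signalling, mating type alpha and meiosis stood 0.34, 0.36 and -0.37 from arrays 1 and 3. With quantile normalization, oxidative phosphorylation (adjusted p = 0.00103), the vacuolar ATPase (0.0185) and amino acid synthesis (0.0397) were called downward. Phospholipid synthesis was called upward among genes above background on all 6 arrays (0.0395). Its median lay 0.43 above that of all genes without deletion array 2. The TCA cycle had a median of 0.01 and a mean of -0.05. The zinc regulon and meiosis medians were -0.08 and -0.23, yet 0.20 and 0.05 relative to all genes. The fry test also gave phosphate signalling and the TCA cycle a downward direction against positive medians. Over all 28 lists, camera called 14 with a preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. The fry test called 27, but it asks whether a list's genes move one way, not whether they differ from the other genes.

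Mitochondrially encoded transcripts showed the deepest falls, a group picked after its members' values were seen. Of 16 tested, 15 were lower in the deletion strain and 12 were not well above background on any deletion array. COB (cytochrome b) was at least 4635-fold lower, ATP6 at least 4229-fold, COX1 at least 1143-fold, the intron gene products AI2 and AI5_ALPHA at least 811-fold and 651-fold, COX3 at least 289-fold, ATP8 at least 143-fold and Q0297 at least 142-fold. OLI1, an ATP synthase subunit, had a wild-type signal of 7.36, was at least 26478-fold lower, and was above background on 2 of 3 deletion arrays. COX2 was above background on all 6 arrays and had a log2 fold change of -7.31 ± 0.31. Q0017, also above background on all 6, fell least of the 15 (-1.85 ± 0.39, adjusted p = 0.0225, and 0.0698 with quantile normalization), and AI3 was not called (-0.19, adjusted p = 0.697; above background on 2 wild-type arrays and 1 deletion array). The list median was -9.27, or -7.24 with dim genes at their bound (camera adjusted p = 3.1e-08, and adjusted p = 0.132 with an estimated correlation). As the list was picked for its falls, these p-values are no independent evidence of a fall.

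**Figure D4:**
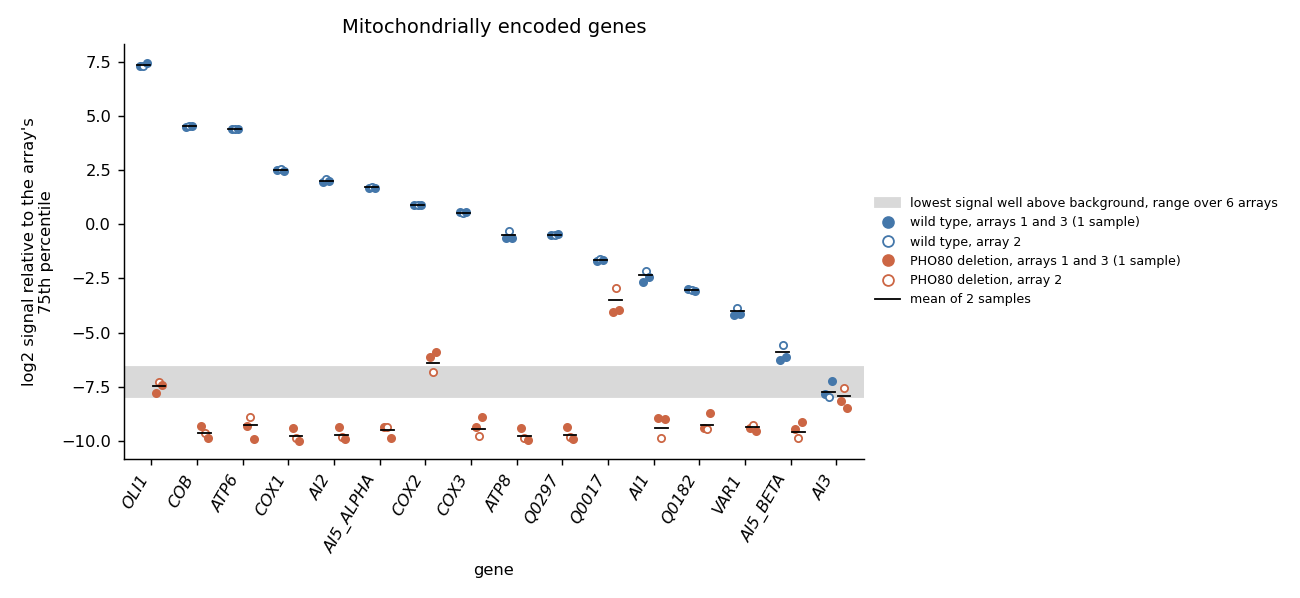
Log2 signal relative to each array's 75th percentile (y axis) for the 16 tested mitochondrially encoded genes (x axis, ordered by wild-type signal), with colours, points, bars and band as for the PHO regulon. Wild-type OLI1 stood at 7.36, whereas 12 genes were not well above background on any deletion array.

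Among the genes always reported, the actin gene ACT1 had a log2 fold change of 0.08 ± 0.11 (adjusted p = 0.583). It became -0.35 with quantile normalization (adjusted p = 0.0348) and was 0.09 without deletion array 2. URA3, an auxotrophic marker that BY4741 lacks, was bright in both strains (3.75 and 5.78) and rose by 2.02 ± 0.21. HIS3, LEU2 and MET17, the other markers, were not well above background on any array.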

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

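The fit with 6 arrays was the design fixed in advance; those with 6 arrays and the block and with the wild type as 1 sample were chosen after the data were seen. PHO80 was lower and the PHO regulon higher in every fit in which they were tested. PHO80 is not tested where genes must be above background on all 6 arrays. The PHO regulon median lay between 2.27 and 2.83, with a preset-correlation camera adjusted p of at most 2.12e-07 over 18 alternatives. PHO80 ranged from -7.04 to -3.01, the latter with normexp background correction and its offset of 50, which used median spot and background signals because the files hold no mean signal. Signal over background limits the measured size of such falls. Over the 67 named genes with a value, 1251 of 1328 alternative values kept direction and side of the threshold. Most of these genes were picked by the size or p of their change in the main fit. Their stability therefore does not carry over to all called genes. With Welch's test on 2 samples per strain only 1 gene was higher and 0 lower (1 at least 2-fold), although 1284 had an unadjusted p under 0.05 and limma called 3152. PHO80 then had an adjusted p of 0.0933 at -6.91. All 3152 called genes were among the calls of the 6-array fit, with 1596 higher and 2629 lower. With the wild type as 1 sample, 519 were higher and 1130 lower. Leaving out 1 array gave 523 to 2200 higher and 1122 to 3289 lower genes, the extremes without wild-type array 2 and without deletion array 2, where the lone sample is assumed to vary like the other strain. The cause was not tested. The lists called went from 14 to 0 with an estimated correlation and to 27 by fry, and stayed between 12 and 16 elsewhere. Over the 28 lists, 485 of 503 values kept direction and side of the threshold. With quantile normalization ACT1 turned to -0.35, the TCA cycle to -0.12 and the zinc regulon to -0.0463 relative to all genes. Meiosis and sporulation, at 0.05, turned to -0.15 without a filter and to -0.0143 with 6 arrays, with or without the block, and ranged from -0.11 (without deletion array 2) to 0.067 with 1 array left out. The cause was not tested.

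Deviations from the strain means correlated at -0.116, -0.08 and 0.0101 across genes for replicates 1, 2 and 3, which gave no sign of pairing. The wild-type arrays differed by little more than spot noise, so these correlations cannot tell whether the samples were paired. With the replicate block, 1132 genes were higher and 2212 lower, the PHO regulon had 19 and 1, and the autophagy and mating type a lists were no longer called (12 lists called). With 6 arrays and the block the counts were 1485 and 2486, and 20 and 2 in the PHO regulon. Some choices listed in advance gave no value. Averaging a gene's probes changes nothing with 1 probe per gene, slide and strain cannot be separated, and probe names do not show which probes paralogs share.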

Other observations

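Further gene groups were put together after the data were seen. Where a list was chosen for the changes of its members, its adjusted p is no independent evidence. Of 19 oxidative stress defence genes 12 rose and 1 fell, with SRX1 (sulfiredoxin) up by 3.34 ± 0.31, AHP1 (a peroxiredoxin) by 2.72 ± 0.13 and TSA1 by 2.04 ± 0.22 (camera adjusted p = 5.61e-06, and adjusted p = 0.141 with an estimated correlation). This list was chosen because some members were among the largest rises. Of 32 proteasome genes 15 rose and none fell, with log2 fold changes of 1.02 for RPT3 and 1.04 for RPT1 (adjusted p = 5.61e-06, and adjusted p = 0.132 with an estimated correlation). Without wild-type array 2 only 3 proteasome genes rose, and RPT3 and RPT1 were not called (adjusted p = 0.0702 and 0.0761). Without deletion array 2, 28 rose and 3 fell, and of the oxidative stress genes 16 rose and 3 fell. Of 18 aminoacyl-tRNA synthetase genes 11 fell and none rose, with SES1 at -2.33 ± 0.11 (adjusted p = 0.00407, and adjusted p = 0.141 with an estimated correlation), and 17 fell and 1 rose without deletion array 2. Mitochondrial ribosomal protein genes, 11 higher and 5 lower of 56, were not called (camera adjusted p = 0.0545). With quantile normalization they had 17 and 5, and with median centring 14 and 3. Thiamine genes, chosen from the falls, had 9 lower and 2 higher of 18 (8 and 1 without wild-type array 2, 14 and 2 without deletion array 2; adjusted p = 0.0249, and adjusted p = 0.222 with an estimated correlation). PHO3, an acid phosphatase gene that acts on thiamine phosphates, had a log2 fold change of -5.06 ± 0.27, and the near-identical THI5, THI11, THI12 and THI13 cannot be separated with certainty (THI13 was not called with normexp background correction, adjusted p = 0.0526).

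Within lists that were not called as a whole, some genes changed strongly, named after their values were seen. The gluconeogenic gene FBP1 (-4.06 on the log2 scale) and the lactate transporter gene JEN1 (-2.60) fell. So did the mitotic cyclin gene CLB2 (at least 19.5-fold, above background on 1 of 3 deletion arrays), the G1 cyclin gene CLN3 (-3.37) and SWI5 (-2.86), whereas the histone gene HTB2 rose by 1.87. The branched-chain amino acid genes BAT1, LEU1 and ILV5 fell (-4.34, -3.71 and -2.75). The alpha pheromone gene MF(ALPHA)1 was at least 19.1-fold lower, below background on all deletion arrays. PDX1, the neighbour of XKS1 in the reference order, rose by 2.93 ± 0.27, and SKI6 on the other side fell (-1.13 ± 0.12, not called without wild-type array 2, adjusted p = 0.0863, and -0.50 with quantile normalization).

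For the mitochondrially encoded transcripts, the test on unequal falls was chosen after the values were seen, and that on neighbouring spots before its own values. The retrograde list was put together after the mitochondrial falls and the medians of 2 lists that share members with it had been seen, but before the values of its own genes. A candidate explanation is that the deletion strain had lost mitochondrial gene products, for example with its mitochondrial DNA. COX2 and Q0017 were above background on all 3 deletion arrays and OLI1 on 2, which goes against a complete loss. Other RNA bound by their probes was not tested. If such products were lost, the other changes in the deletion strain, those of the gene lists among them, cannot be told apart from effects of that loss. The nuclear retrograde genes rise when mitochondrial function is lost, and most went the way such a loss needs. Of the 7 genes 5 rose, with DLD3 up by 1.94 ± 0.11 and CIT2 by 0.63 ± 0.11. ACO1 and PYC1 were not called (-0.35 and -0.12). The median of the retrograde genes lay 1.12 above that of all genes (camera adjusted p = 0.00672, and adjusted p = 0.141 with an estimated correlation). Without wild-type array 2 only 2 of the 7 rose and CIT2 was not called (adjusted p = 0.376), nor was CIT2 with quantile normalization (0.18, adjusted p = 0.27). A defect of the slide at these spots was argued against, since the 2347 neighbouring spots lay 0.0213 from the median of all spots, within the bound of 0.5 set in advance. A lower yield of all mitochondrial RNA by 1 factor would give equal falls, and the falls were unequal. OLI1, COB, ATP6, COX1, AI2 and AI5_ALPHA had bounds of 9.35 to 14.69 on the log2 scale, all 6 more than 2 beyond the fall of COX2 (-7.31 ± 0.31), and Q0017 fell less still (-1.85 ± 0.39). This speaks against 1 factor but rests on COX2 and Q0017, the 2 fallen genes above background on all 6 arrays. Other RNA bound by their probes could keep a signal there, which was not tested, so such a yield stays open, as does a difference between the slides.

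For deletion array 2, both tests were chosen after its distance had been seen. It differed by over 1 on the log2 scale from the mean of arrays 1 and 3 at 459 genes, 437 of them lower. A shift that depends on intensity does not account for this, as the squared difference stayed at 170 times spot noise after a smooth trend was removed (183 before). A wild-type or mixed sample is argued against because PHO80 was not above background on it and the 1919 genes called at least 2-fold without it and above background on the other 5 arrays lay at a median of 0.01235 of the way from arrays 1 and 3 to wild type. A separate culture or RNA preparation was not tested and may be the source.

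For the number of genes called over 6 arrays, the split by strain called 4225 genes, 1 of 10 splits with as many, and the highest of the others called 0. With 10 splits the share cannot fall under 0.05. By limma, the 2 samples per strain gave 3584 genes at an unadjusted p under 0.05.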
